A study of Arabidopsis thaliana with 57 samples.

How the data were processed

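The data are strand-specific RNA sequencing libraries from young flowers of Arabidopsis thaliana, 57 libraries in all. Per the labels' protocols, total RNA of each replicate was pooled from several lines of one flower phenotype, treated with DNase, depleted of ribosomal RNA and made into stranded total RNA libraries that were sequenced on a HiSeq X-Ten. The labels place each library in batch A or batch B, and the batches differ in their index primers, combinatorial indexes in A and unique dual indexes in B. Batch A has 20 libraries in 7 groups and batch B has 37 libraries in 13 groups. A group is a genotype with its transgene cassette, a flower phenotype and a batch. There are 17 groups of 3 libraries and 3 groups of 2. The labels name the phenotypes Wt, sMf and rMf, the cassettes AGP//AGe, ARE//AGe and Ctr//AGe, and the lines M317 and M318 without spelling these names out, and they are used here as given.

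The deposited table holds, per the file headers, raw read counts of each strand over 2 regions of chromosome 4, which make 4 region-by-strand features, together with the total, uniquely mapped, multiply mapped and mapped reads of each library. The first region is called the AG enhancer (AGe) in the header. The second is called the AG promoter (AGp) or M2, and the header does not say for which libraries it was counted as which. Per the submitters' processing notes, the genome build was TAIR10 and the tools included HISAT2 and HTSeq 0.13.5. Their settings, and whether a read over several places was kept, are not given in the sources used here. The authors also deposited normalized values as RPM, which the header describes as scaled to mapped reads. Recomputed from the counts, these RPM values equal count / uniquely mapped reads × 1000000, with a largest gap of 0.0. The deposited percent of mapped reads lies within 0.5 points of mapped over total reads for all but 3 batch A libraries, and a median of 2.93 points above it in batch B. That percentage was used only to describe the libraries. In Col AGP//AGe sMf replicates 2 and 3, the library's own mapped reads were 88.6% and 102% of its total reads. The other library's mapped reads were 94.5% and 95.3% of those totals, and these are the deposited percentages of replicates 2 and 3. Which entries of the table are out of place is not given in the sources used here. Library sizes were the uniquely mapped reads as deposited, 33759576 and 34322717, and an alternative exchanged them.

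Reads from a cassette copy of a region and from the endogenous locus map to the same coordinates and cannot be told apart in these counts. A region present in many copies elsewhere would lose reads to the multiply mapped class. No gene other than AG is represented in the table, so the gene lists fixed beforehand (floral organ identity, RNA-directed DNA methylation and others) have no measured member besides AG itself and were not tested.

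All comparisons used the raw counts with the uniquely mapped reads as library sizes. The quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) was fitted to all 57 libraries with a mean for each of the 20 groups and no block, so that the groups share 1 estimate of the spread with 37 residual degrees of freedom. The common dispersion was 0.0364, a biological coefficient of variation of 19.1%. It was used for all features, with no trend and a prior count of 0.125. p-values were adjusted by Benjamini-Hochberg over the 4 features within a comparison, and an adjusted p under 0.05 is called a difference. Standard errors were taken from the log2 fold change and its F statistic. Differences of differences were tested as contrasts of 4 groups in the same fit. Each pairwise comparison also received a two-sided exact permutation test of the difference of mean RPM. That test has 20 splits for 3 libraries against 3 and 10 for 2 against 3, so its smallest p is 0.1, which 65 of 120 tests reached. The exact test cannot pass 0.05 in any of these comparisons, and the calls rest on the spread shared by all groups. Since replicates are RNA pools of lines, p-values measure the spread between pools.

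The groups, 30 of the 36 comparisons, the test, the features named (all 4, because the table has few) and the first set of alternative settings were fixed before the data were examined. A further 6 comparisons were added afterwards: each mutant with ARE//AGe and Wt flowers against Col with ARE//AGe, and the difference between each mutant and Col in the change with the cassette. In each of the 36 comparisons the groups belong to 1 batch, except where Col ARE//AGe is compared between the batches. Alternatives were another prior count, 1 batch or only the compared groups in the fit, each replicate left out, a replicate block, robust moderation, DESeq2 1.42.0, and adjustment over all comparisons together. Those added after seeing the data were all mapped reads as library size, the depths of both Col AGP//AGe sMf libraries above exchanged, libraries with over 20% multiply mapped reads left out, limma 3.58.1 on log2(RPM + 0.0280), and each library left out alone. No pair of libraries held identical values.

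Simulated tables with the real library sizes, group means and common dispersion were run through the same code, 100 for each setting and 4 features in each. The simulated fold was applied to all 4 features at once, which eases the adjustment within a comparison. The further spread of single features was not simulated. It was largest for AGp sense reads (quasi-dispersion 2.42), whose called shares below are therefore likely too high. For AGP//AGe sMf against Wt with no change, 2% of tables called AGe sense reads, 4% AGe antisense reads and 1% each promoter strand. With a simulated 2-fold change, the called shares were 98%, 95%, 66% and 48% for AGe sense, AGe antisense, AGp sense and AGp antisense reads. For hdp2-1 ARE//AGe sMf against Wt, a 2-fold change was called in 97%, 93%, 83% and 74% of tables in the same order.

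Uniquely mapped reads ranged from 16259524 to 56584186 per library. A feature with no reads is compatible with up to 3 counts, which is 0.0530 to 0.185 RPM in a single library. Where a whole group had no reads, the fold against it was computed from 3 counts over the summed depth of the group and is a lower bound that scales with that depth. Where a group had 1 to 3 reads, the ratio is given with its exact 95% counting interval. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. Annotation came from TAIR10.1, whose coordinates for chromosome 4 were compared with the boundaries in the table. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.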

Results

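Reads of both strands were counted over 2 regions at AGAMOUS (AG, AT4G18960), the MADS-box gene that specifies stamens and carpels. AG lies on the plus strand of chromosome 4, from 10382856 to 10388539, so plus-strand reads are sense reads. Sense and antisense refer to AG at its own locus, and the counts do not give the orientation of AGe within a cassette. The enhancer region (AGe) runs from 10384147 to 10387145 (2999 bp, 28.6% GC). It coincides base for base with intron 2 of 1 of the 4 annotated AG transcripts. The other transcripts have an exon of 90 bp inside it, from 10386982 to 10387071, so sense reads over the region can come from spliced or unspliced AG RNA. The promoter region (AGp) runs from 10380701 to 10382800 (2100 bp, 28.6% GC). It is intergenic and ends 56 bp before the annotated start of AG. The header of the deposited table calls this region AG promoter or M2 and does not say which name goes with which libraries, so a promoter read here is a read of that column. Promoter differences between groups therefore assume that the same region was counted in both. Neither region overlaps another annotated gene.

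**Figure D1:**
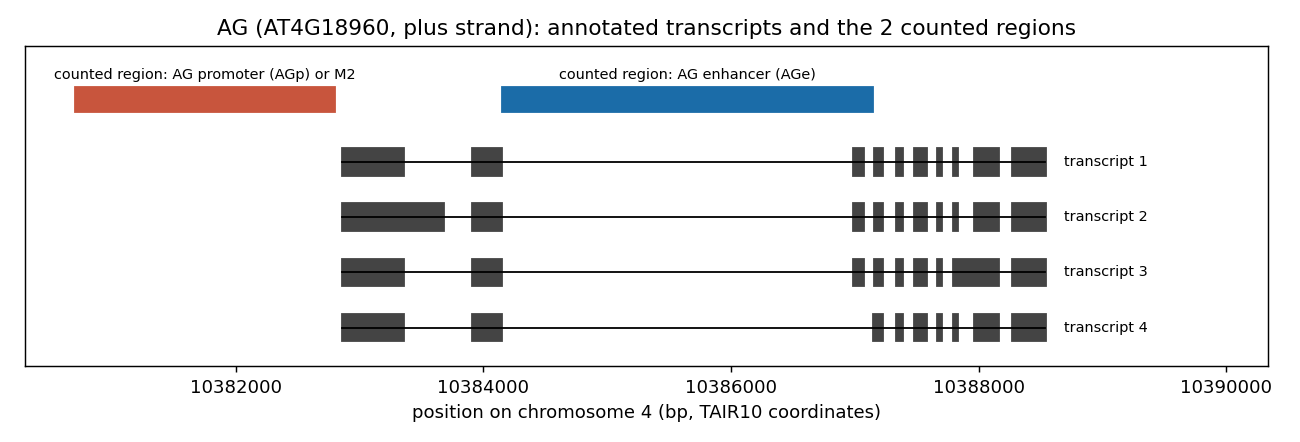
Map of AG on chromosome 4 (x axis, position in bp) with the 4 annotated transcripts (boxes, exons; lines, introns) and the 2 counted regions. The enhancer region fills intron 2 of transcript 4, and the promoter region ends 56 bp before the gene.

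The libraries came from young flowers of plants transformed with cassettes that combine AGe with another element (AGP//AGe, ARE//AGe or Ctr//AGe), and from plants without a cassette. According to the series title, ARE is an element that protects a regulatory sequence against silencing guided by noncoding RNA, and the libraries were made to profile that RNA. Batch A held Col (the Columbia background) with AGP//AGe and flowers scored Wt, rMf or sMf, Col with ARE//AGe, Col with Ctr//AGe, and the lines M317 and M318. Apart from AGP//AGe, all batch A groups had Wt flowers. Batch B held Col and the mutants suvh1-2, hdp1-1 and hdp2-1, each without a cassette and with ARE//AGe. Col with ARE//AGe and all batch B plants without a cassette had Wt flowers. The mutants with ARE//AGe had Wt or sMf flowers, and hdp1-1 and hdp2-1 also rMf flowers. SUVH1 is a reader of methylated DNA, and HDP1 and HDP2 belong to a complex that counteracts silencing. Uniquely mapped reads were 23958021 to 41517984 per library in batch A and 16259524 to 56584186 in batch B. Multiply mapped reads made up 6.46% to 36.5% of mapped reads. They exceeded 20% in 7 libraries with ARE//AGe: hdp1-1 sMf replicates 1, 2 and 3, hdp1-1 Wt replicates 2 and 3, hdp1-1 rMf replicate 2, and suvh1-2 sMf replicate 3. AGe sense reads numbered 70 to 631 per library, and the promoter region never held more than 61. Levels are counts divided by uniquely mapped reads and multiplied by 1000000 (RPM), given as mean ± SD over libraries, and n = 3 unless another n is given. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

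ARE//AGe in Col went with abundant reads over the enhancer on the strand antisense to AG. In batch A, AGe antisense reads were 12.8 ± 0.719 RPM with ARE//AGe and 1.25 ± 0.285 RPM with Ctr//AGe, a 10.1-fold difference (log2 3.33 ± 0.30 SE, adjusted p = 1.479e-13). Sense reads did not differ detectably, at 14.5 ± 0.640 against 12.4 ± 1.01 RPM (log2 0.22 ± 0.19 SE, 95% interval -0.16 to 0.60, adjusted p = 0.344), though they were called with only these groups in the fit (adjusted p = 0.0225). Antisense reads were therefore 46.8% ± 0.751 of the enhancer reads with ARE//AGe and 9.24% ± 2.56 with Ctr//AGe. No promoter read was seen with ARE//AGe, and 1 in all with Ctr//AGe.

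In batch B the same cassette was set against Col without a cassette. AGe antisense reads rose from 0.253 ± 0.0545 to 14.3 ± 1.64 RPM, a 54.5-fold difference (log2 5.77 ± 0.37 SE, adjusted p = 5.283e-19). Sense reads were lower with the cassette, 5.31 ± 0.493 against 7.87 ± 0.980 RPM (log2 -0.56 ± 0.20 SE, adjusted p = 0.0135). The antisense share was 72.9% ± 0.582 with ARE//AGe and 3.18% ± 0.951 in Col. The promoter region held 4 reads in the 3 libraries with the cassette and none in Col. The sense call was lost without Col replicate 3 (log2 -0.46, adjusted p = 0.0853) or without ARE//AGe replicate 1 (log2 -0.50, adjusted p = 0.0605).

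Col ARE//AGe was the 1 group present in both batches. Its antisense level did not differ detectably between B and A (95% interval -0.35 to 0.69, log2 0.17 ± 0.26 SE, adjusted p = 0.512). Its sense level was 2.72-fold lower in B (log2 -1.44 ± 0.20 SE, adjusted p = 1.663e-08).

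**Figure D2:**
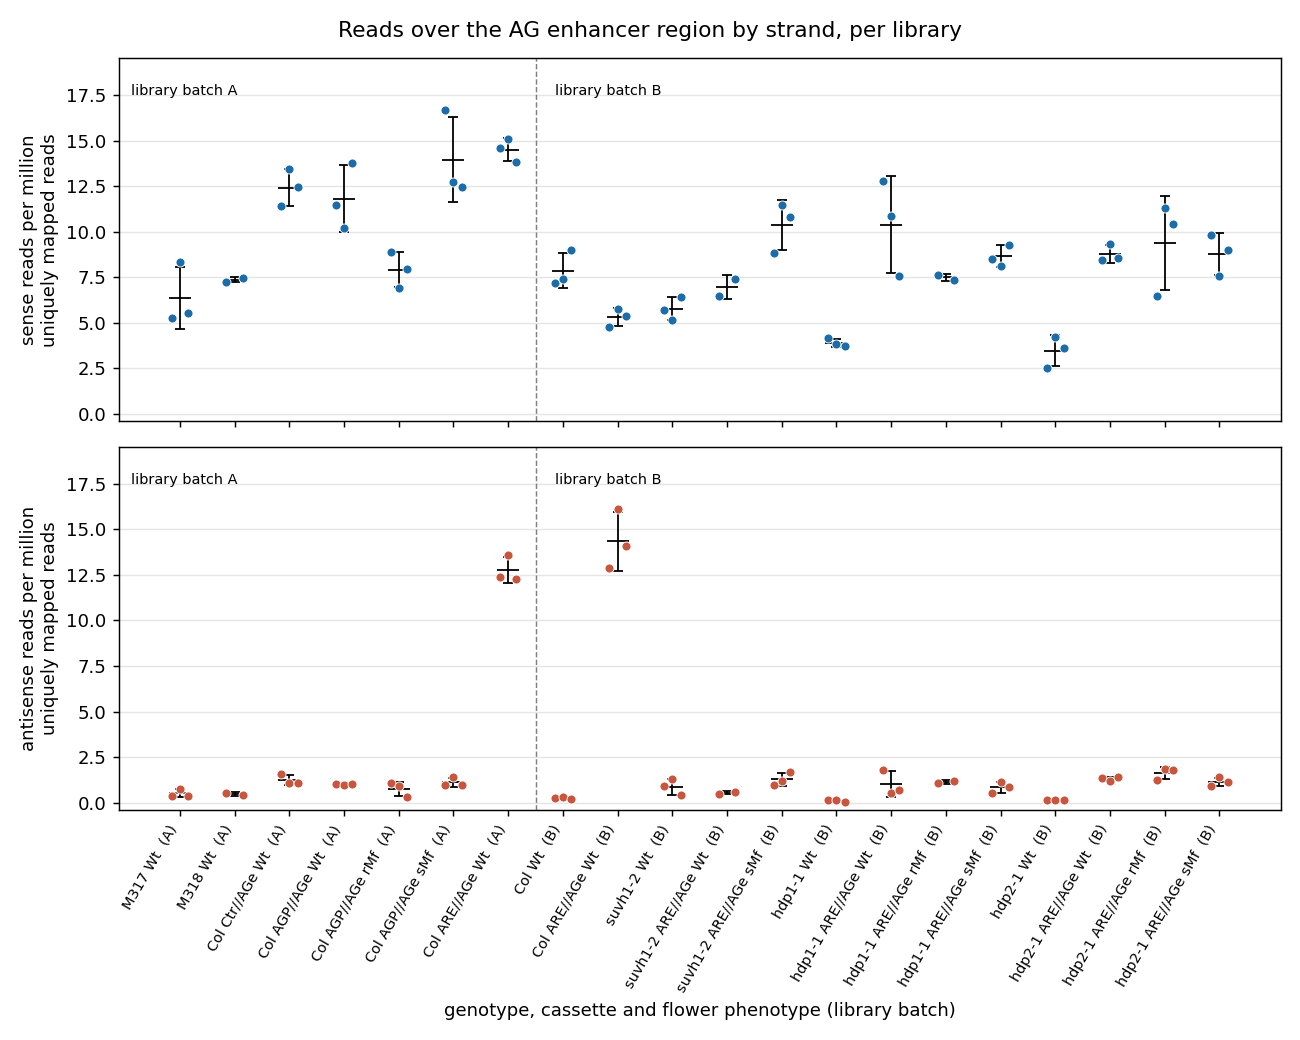
AGe sense reads (top) and antisense reads (bottom) in RPM (y axis) for each library by group (x axis), with batch in brackets. Points are libraries and black bars are mean and SD. The 6 Col ARE//AGe libraries hold 12.3 to 16.1 RPM of antisense reads, and the 22 mutant libraries with ARE//AGe hold 0.505 to 1.86 RPM.

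The AGP//AGe cassette, set against Ctr//AGe in batch A, went with reads in the column for AG promoter or M2. If that column was counted over different regions in the AGP//AGe and Ctr//AGe libraries, the promoter folds below do not compare like with like. The 9 AGP//AGe libraries held 2 to 40 promoter reads each, 138 in all. Sense promoter reads were 0.238 ± 0.214 RPM with Wt flowers, 0.147 ± 0.152 RPM with rMf flowers and 0.406 ± 0.418 RPM with sMf flowers. Ctr//AGe had none, so these levels were at least 7.03-fold, 4.34-fold and 12.0-fold higher (adjusted p = 0.00712, 0.0200 and 0.000676). Antisense promoter reads were 0.137 ± 0.108, 0.197 ± 0.0651 and 0.217 ± 0.110 RPM in the same order, against 1 read with Ctr//AGe. The ratios of 13.0, 18.1 and 19.4 have 95% counting intervals that start at 2.00, 2.92 and 3.13 (adjusted p = 0.00712, 0.00197 and 0.000677). Single libraries carried part of this. Without sMf replicate 2, at 0.889 RPM, the bound for sense reads fell to 4.86-fold. Without Wt replicate 3 it fell to 3.77-fold. Without rMf replicate 3 it fell to 2.02-fold and the call was lost (adjusted p = 0.107), as it was without Ctr//AGe replicate 1 (adjusted p = 0.0536). Without Ctr//AGe replicate 2 the antisense bounds were 2.63-fold, 3.78-fold and 4.15-fold. Without Wt replicate 1 the Wt antisense call was lost (adjusted p = 0.112). With only batch A in the fit, both promoter calls of Wt were lost (adjusted p = 0.0968 sense and 0.0589 antisense), as was the sense call of rMf (adjusted p = 0.110). With only the 2 compared groups in the fit, the sense calls of all 3 phenotypes were lost (adjusted p = 0.0643 for Wt, 0.151 for rMf and 0.0615 for sMf), as was the antisense call of Wt (adjusted p = 0.0643).

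Enhancer reads of AGP//AGe differed by flower phenotype on the sense strand. Sense reads were 7.92 ± 0.972 RPM with rMf flowers, 11.8 ± 1.82 RPM with Wt flowers and 14.0 ± 2.34 RPM with sMf flowers. The rMf level was lower than Wt (log2 -0.58 ± 0.19 SE, adjusted p = 0.0168), lower than Ctr//AGe (log2 -0.65 ± 0.19 SE, adjusted p = 0.00296), and 1.76-fold below sMf (sMf minus rMf, log2 0.82 ± 0.19 SE, adjusted p = 0.000405). For sMf against Wt, edgeR called 0 of the 4 features at the adjusted threshold, 0 at an unadjusted p under 0.05, and 0 with DESeq2 and limma. The sMf to Wt sense difference was log2 0.24 (95% interval -0.14 to 0.62). AGe antisense reads were 0.765 ± 0.380 RPM with rMf flowers, against 1.25 ± 0.285 with Ctr//AGe (log2 -0.69 ± 0.34 SE, adjusted p = 0.0485). They did not differ detectably between rMf, Wt (1.03 ± 0.0296 RPM) and sMf (1.12 ± 0.235 RPM) flowers, with adjusted p of 0.414 for rMf against Wt, 0.179 for sMf against rMf and 0.709 for sMf against Wt. The rMf to Wt sense call was lost without rMf replicate 2 (log2 -0.49, adjusted p = 0.122) or Wt replicate 3 (log2 -0.45, adjusted p = 0.149). Neither the rMf to Wt nor the sMf to rMf sense call held with only the compared groups in the fit (adjusted p = 0.259 and 0.0785). The rMf to Ctr//AGe antisense call was lost with 1 batch or only the compared groups in the fit, with all mapped reads as library size or with adjustment over all comparisons (adjusted p from 0.0697 to 0.157), and without rMf replicate 3 (log2 -0.37, adjusted p = 0.286) or Ctr//AGe replicate 1 (log2 -0.47, adjusted p = 0.227).

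ARE//AGe with Wt flowers and AGP//AGe with sMf flowers did not differ detectably in sense reads over the enhancer (log2 0.06, 95% interval -0.32 to 0.43, adjusted p = 0.769). They differed in the other 3 features. Flower phenotype differs along with the cassette in this contrast, so their parts cannot be told apart. Antisense enhancer reads were 11.3-fold higher with ARE//AGe (log2 3.50 ± 0.30 SE, adjusted p = 3.15e-14). Promoter reads were at least 14.7-fold lower on the sense strand and 7.82-fold lower on the antisense strand (adjusted p = 9.578e-05 and 3.949e-05), if the same region was counted with both cassettes. Without AGP//AGe sMf replicate 2 the sense bound was 5.94-fold, and without ARE//AGe replicate 1 the bounds were 9.27-fold and 4.95-fold.

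M317 and M318 had fewer enhancer reads than Ctr//AGe on both strands. Sense reads were 6.38 ± 1.69 RPM in M317 and 7.36 ± 0.135 RPM (n = 2) in M318. These were 1.95-fold and 1.69-fold below Ctr//AGe (log2 -0.96 ± 0.19 SE and -0.75 ± 0.22 SE, edgeR adjusted p = 4.434e-05 and 0.00404). Antisense reads were 0.508 ± 0.221 RPM in M317 and 0.481 ± 0.0965 RPM (n = 2) in M318, lower by log2 -1.31 ± 0.37 SE and -1.39 ± 0.42 SE (edgeR adjusted p = 0.00176 and 0.00404). Without replicate 1 of both M317 and Ctr//AGe, the M317 antisense call was lost and its sense call was kept. The 5 libraries had a count of 0 in the column for AG promoter or M2, which allows up to 0.0193 RPM over their summed depth. Whether M2 was the region counted in these lines is not given in the sources used here. Between M318 and M317, edgeR called 0 of 4 features, 0 at an unadjusted p under 0.05, and DESeq2 and limma 0 (sense log2 0.21, 95% interval -0.23 to 0.64). Leaving out either M318 replicate leaves 1 M318 library, so the stability of its sense and antisense calls against Ctr//AGe cannot be told. Without M318 replicate 2 the antisense difference from Ctr//AGe was log2 -1.20.

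Without a cassette, hdp1-1 and hdp2-1 had fewer AGe sense reads than Col, and suvh1-2 had more reads of other kinds. Sense reads were 3.90 ± 0.218 RPM in hdp1-1 and 3.47 ± 0.850 RPM in hdp2-1, against 7.87 ± 0.980 RPM in Col. These are 2.01-fold and 2.27-fold differences (log2 -1.01 ± 0.20 SE and -1.19 ± 0.20 SE, adjusted p = 3.175e-05 and 2.297e-06). Antisense reads in both were 10 per 3 libraries against 29 in Col, and the difference did not pass (adjusted p = 0.111 and 0.247). Both were called with only the compared groups in the fit (adjusted p = 0.02925 and 0.0487), and that of hdp1-1 with limma (adjusted p = 0.00810). In suvh1-2 the AGe antisense reads were 0.880 ± 0.433 RPM, 3.35-fold above Col (log2 1.74 ± 0.43 SE, adjusted p = 0.000428). Sense reads were 5.77 ± 0.628 RPM (log2 -0.45 ± 0.20 SE, adjusted p = 0.0278). That sense call was lost without Col replicate 3 (adjusted p = 0.124), suvh1-2 replicate 1 (adjusted p = 0.0571) or suvh1-2 replicate 2 (adjusted p = 0.0992), with log2 of -0.34, -0.44 and -0.38. It was also lost with only batch B (adjusted p = 0.0598) or the compared groups (adjusted p = 0.1055) in the fit and with adjustment over all comparisons (adjusted p = 0.0589). Promoter reads in suvh1-2 were 9 to 17 per library, at least 8.05-fold (sense) and 14.6-fold (antisense) above Col, which had none (adjusted p = 0.00307 and 1.908e-06). Without Col replicate 2, the deepest library, the bounds were 3.92-fold and 7.11-fold. The 9 libraries of Col, hdp1-1 and hdp2-1 held 2 promoter reads in all.

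**Figure D3:**
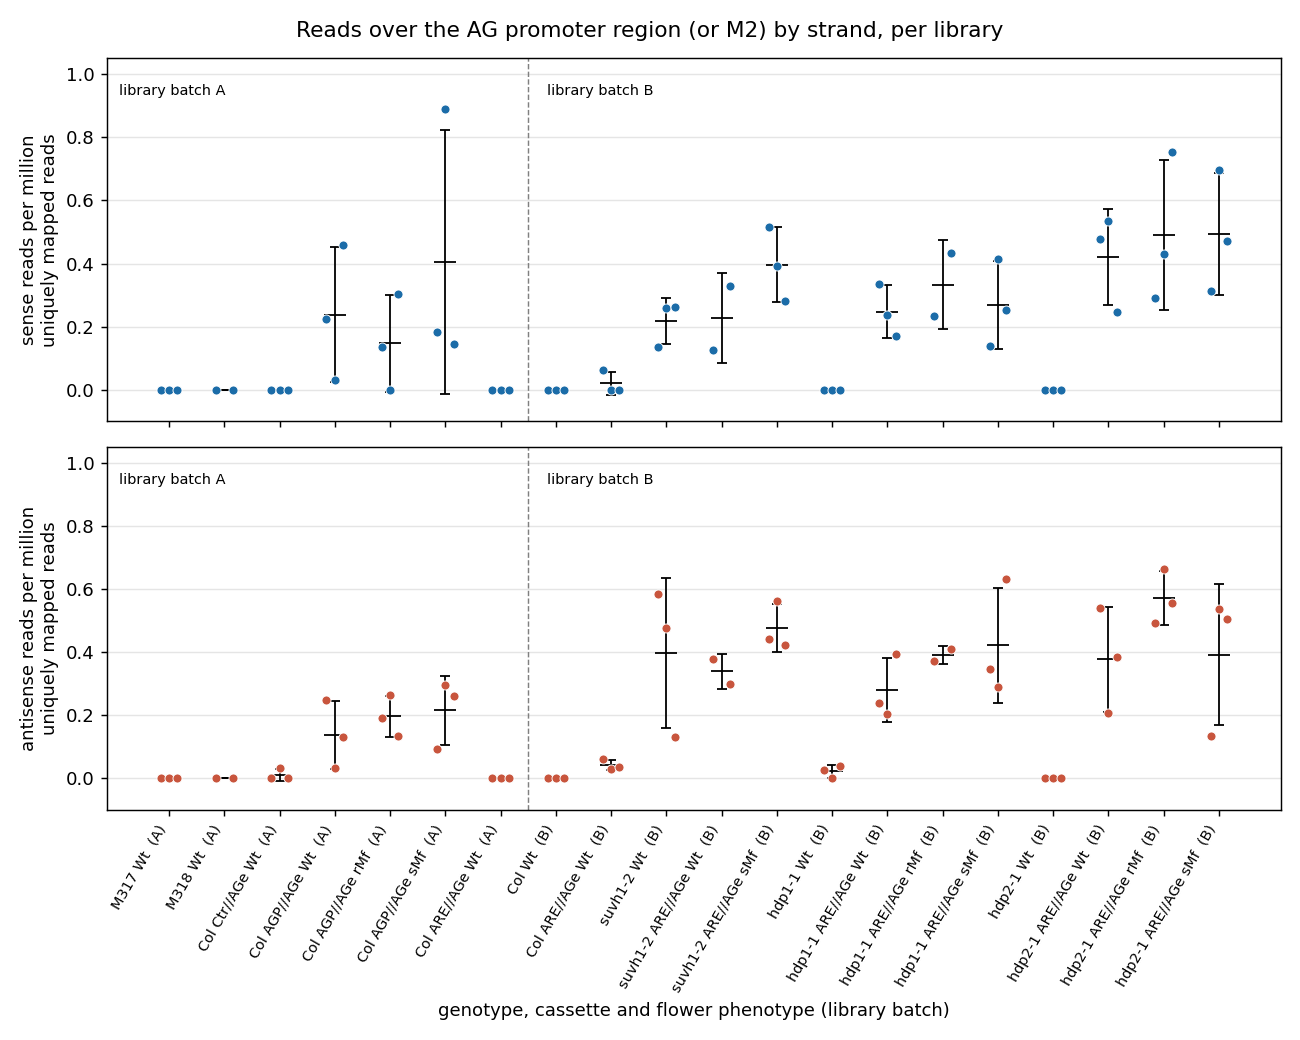
Promoter region sense reads (top) and antisense reads (bottom) in RPM (y axis) for each library by group (x axis), with batch in brackets. Points are libraries and black bars are mean and SD. All 3 suvh1-2 libraries without a cassette hold promoter reads (9 to 17 each), and the 22 mutant libraries with ARE//AGe hold 10 to 61 each.

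In hdp1-1 and hdp2-1, ARE//AGe with Wt flowers went with more reads of all 4 kinds. AGe sense reads were 10.4 ± 2.65 RPM in hdp1-1 and 8.78 ± 0.480 RPM in hdp2-1 with the cassette, 2.68-fold and 2.54-fold above the same mutant without it (adjusted p = 3.326e-08 and 8.843e-08). AGe antisense reads were 1.00 ± 0.711 and 1.32 ± 0.116 RPM, 9.28-fold and 9.78-fold higher (log2 3.21 ± 0.49 SE and 3.29 ± 0.48 SE, adjusted p = 1.172e-07 and 8.843e-08). Without hdp1-1 ARE//AGe replicate 1, at 1.82 RPM, the hdp1-1 ratio of means was 5.55 in place of 9.36. Promoter reads of both strands together were 0.527 ± 0.0729 and 0.798 ± 0.200 RPM with the cassette, and 0.0229 ± 0.0208 and 0 RPM without it. All 4 features were called in each mutant, with the largest adjusted p at 0.00145. In suvh1-2 edgeR called 0 of 4 features between plants with ARE//AGe and Wt flowers (n = 2) and plants without it, 0 at an unadjusted p under 0.05, and DESeq2 and limma 0. AGe antisense reads there were 0.553 ± 0.0683 RPM with the cassette (n = 2) and 0.880 ± 0.433 RPM without, and the 95% interval of the log2 difference was -1.52 to 0.19. Promoter reads were 0.567 ± 0.0877 RPM (n = 2) and 0.617 ± 0.194 RPM.

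Each mutant with ARE//AGe was set against Col with ARE//AGe, whose flowers were all Wt. The contrasts of sMf mutants therefore differ from Col in flower phenotype as well as genotype. Only the comparisons added later have the same phenotype on both sides. With sMf flowers in the mutant, AGe antisense reads were 11.1-fold lower in suvh1-2 (1.29 ± 0.358 RPM), 17.2-fold lower in hdp1-1 (0.840 ± 0.301 RPM) and 12.2-fold lower in hdp2-1 (1.15 ± 0.231 RPM) than the 14.3 RPM of Col. The log2 differences were -3.47, -4.11 and -3.61 (SE 0.30, 0.33 and 0.31, adjusted p = 3.263e-14, 1.421e-15 and 1.825e-14). Sense reads were higher in each, by 1.95-fold, 1.62-fold and 1.65-fold (adjusted p = 2.158e-05, 0.00139 and 0.000746). The Col ARE//AGe sense level they were set against, 5.31 ± 0.493 RPM, was itself low. It lay below Col without a cassette (7.87 ± 0.980 RPM) and 2.72-fold below Col ARE//AGe of batch A. Promoter reads were higher on both strands in all 3 mutants, with the largest adjusted p at 0.00853. Without replicate 2 of both groups, the hdp1-1 sense promoter call was lost. Col ARE//AGe had 1 sense and 3 antisense promoter reads, and the sense ratios of 29.9, 20.1 and 40.7 have 95% counting intervals from 5.06, 3.22 and 6.95 upwards. Without Col ARE//AGe replicate 1, which held the 1 sense read, Col had none and the levels were at least 8.06-fold, 5.45-fold and 10.03-fold higher. In the hdp1-1 sMf libraries 31.1% ± 4.65 of mapped reads were multiply mapped, against 13.4% ± 2.75 in Col ARE//AGe. With all mapped reads as library size the hdp1-1 sense difference did not pass (log2 0.37, adjusted p = 0.105). In the comparisons added later with Wt flowers, AGe antisense reads were lower by 25.8-fold in suvh1-2 (n = 2), 13.3-fold in hdp1-1 and 10.8-fold in hdp2-1 (adjusted p = 8.147e-15, 7.798e-15 and 5.505e-14). Without hdp1-1 replicate 1 the hdp1-1 ratio of means was 24.1 in place of 14.3. Sense reads were higher in hdp1-1 and hdp2-1 (adjusted p = 2.525e-05 and 0.000979) and did not pass in suvh1-2 (log2 0.38, adjusted p = 0.0869, or 0.0226 with only the compared groups in the fit).

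Flower phenotype within the mutants carrying ARE//AGe was associated with enhancer reads in suvh1-2. With sMf flowers suvh1-2 had 10.4 ± 1.38 RPM of AGe sense reads against 6.95 ± 0.652 RPM with Wt flowers (n = 2) (log2 0.58 ± 0.22 SE, edgeR adjusted p = 0.0209). Antisense reads were 1.29 ± 0.358 against 0.553 ± 0.0683 RPM (n = 2), 2.34-fold more (log2 1.22 ± 0.39 SE, edgeR adjusted p = 0.0133). Promoter reads did not differ detectably (edgeR adjusted p = 0.298 for both strands). Both calls were lost without Wt replicate 2 (log2 0.49 and 1.10, adjusted p = 0.181 and 0.151) or sMf replicate 3 (log2 0.55 and 0.98, both adjusted p = 0.0537). The sense call was also lost without sMf replicate 2 (log2 0.50, adjusted p = 0.0798). With all mapped reads as library size, or only batch B in the fit, the sense call was lost as well (log2 0.52 and 0.58, adjusted p = 0.0803 and 0.0538).

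For hdp1-1 and hdp2-1, no difference of sMf or rMf from Wt flowers passed the test. Across these 4 comparisons edgeR called 0 features, and DESeq2 and limma called 0. At an unadjusted p under 0.05 there was 1, AGe sense reads of hdp1-1 rMf (7.50 ± 0.185 RPM, n = 2) against Wt (10.4 ± 2.65 RPM). It had log2 -0.48 ± 0.22 SE and an edgeR adjusted p of 0.13. Without hdp1-1 Wt replicate 3 it was called (log2 -0.66, adjusted p = 0.0190). The sMf to Wt difference in AGe antisense reads was log2 -0.37 (95% interval -1.09 to 0.35) in hdp1-1 and -0.18 (-0.85 to 0.48) in hdp2-1. The sMf to Wt change did not differ detectably between hdp1-1 and hdp2-1 (AGe sense log2 -0.28 ± 0.27 SE, adjusted p = 0.719). It was larger in suvh1-2 than in hdp1-1 for sense reads (log2 0.86 ± 0.29 SE, adjusted p = 0.0101) and for antisense reads (log2 1.59 ± 0.53 SE, adjusted p = 0.0101). Against hdp2-1 it was larger for antisense reads (log2 1.41 ± 0.51 SE, adjusted p = 0.0359) and did not pass for sense reads (log2 0.58 ± 0.29 SE, adjusted p = 0.102). Both differences from hdp1-1 were lost without suvh1-2 Wt replicate 2 (log2 0.76 and 1.47, both adjusted p = 0.0628) or hdp1-1 Wt replicate 1 (log2 0.68 and 0.71, adjusted p = 0.0972 and 0.388). The difference from hdp2-1 was lost without any 1 of 7 libraries, with adjusted p from 0.0566 to 0.169. With only the compared groups in the fit, both differences from hdp1-1 were lost (both adjusted p = 0.0819) and the sense difference from hdp2-1 was called (adjusted p = 0.0498). With limma the antisense differences from hdp1-1 and hdp2-1 were lost (adjusted p = 0.0674 and 0.0861), and the latter was lost too with all mapped reads as library size (adjusted p = 0.128) or without the libraries over 20% multiply mapped (adjusted p = 0.0646).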

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

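All tests of explanations in this part, and the comparisons of the cassette's effect between each mutant and Col, were chosen after the values were seen. The differences in the sMf change between mutants were planned.

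The change with ARE//AGe (Wt flowers, against the same background without a cassette) differed between each mutant and Col. For AGe antisense reads the log2 change was smaller than in Col by -6.44 ± 0.57 SE in suvh1-2, -2.55 ± 0.78 SE in hdp1-1 and -2.48 ± 0.77 SE in hdp2-1 (edgeR adjusted p = 7.224e-14, 0.00425 and 0.00514). For AGe sense reads it was larger by 0.83 ± 0.29 SE, 1.98 ± 0.28 SE and 1.90 ± 0.28 SE (edgeR adjusted p = 0.0141, 3.86e-08 and 1.197e-07). The suvh1-2 sense call was lost without suvh1-2 ARE//AGe Wt replicate 3 (log2 0.73, adjusted p = 0.0689), and the hdp1-1 antisense call without hdp1-1 replicate 1 (log2 -2.31, adjusted p = 0.0568). The hdp1-1 and hdp2-1 values rest on no more than 10 antisense reads per 3 libraries of each mutant without the cassette. The suvh1-2 value rests on 2 libraries with the cassette and Wt flowers. Its libraries without a cassette held 9 to 17 promoter reads each, and cassette-bearing plants in those pools stay open below. If present, the suvh1-2 change would not measure the cassette.

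The first pattern is that the mutants with ARE//AGe were unlike Col with ARE//AGe. A lower unique depth through multiply mapped reads raises RPM, so it bears on the higher sense and promoter reads and not on the lower antisense reads, and it is argued against for hdp2-1 sMf, which had a smaller multiply mapped share than Col ARE//AGe and AGe sense reads higher by a log2 of 0.718 ± 0.198 SE. For hdp1-1 sMf it may account for part of the sense difference, because all mapped reads as library size moved the log2 from 0.70 ± 0.20 SE to 0.367 ± 0.222 SE and the call ended with the smaller difference (edgeR adjusted p = 0.105). A candidate explanation that stays open is that the mutants carry a construct unlike that of Col. For both AGe antisense and promoter reads, 16 of the 22 mutant libraries lie within the range of the AGP//AGe libraries. All 3 suvh1-2 libraries without a cassette also lie within both ranges, so in suvh1-2 this match cannot tell another construct from no cassette. The 9 libraries of Col, hdp1-1 and hdp2-1 without a cassette lie below both ranges. They hold 0.0406 to 0.300 RPM of AGe antisense reads and 0 to 0.0406 RPM of promoter reads. In hdp1-1 and hdp2-1 the match thus differs from no cassette, but it cannot tell another construct from an effect of the mutation. The AGP//AGe libraries are of batch A, and the labels give the mutants as ARE//AGe. An effect of the mutations, which the design names, was not tested and stays open.

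The second pattern is the promoter reads of suvh1-2 without a cassette, 9 to 17 in each library. Carry-over spread evenly between libraries is argued against, because suvh1-2 held 42 promoter reads in all and the other 9 libraries without a cassette held 2. The lowest suvh1-2 library was 9.68 times the highest of those 9, but this ratio sets 9 reads against 1 read and has no interval. The level without the cassette was 1.09 times that with it and Wt flowers (n = 2). Similar levels would arise from pools made up of cassette-bearing plants or from the mutation alone, so this ratio cannot tell them apart. ARE//AGe itself went with 4 promoter reads in 6 Col libraries, but with promoter reads in all 22 mutant libraries. An effect of the suvh1-2 mutation was not tested and stays open.

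The third pattern is the lower AGe sense level of Col ARE//AGe in batch B than in batch A. Library size scaling is argued against, because the antisense change exceeded the sense change by a log2 of 1.61 ± 0.33 SE. Antisense reads counted as sense in batch A are argued against as the whole cause, because both strands summed were still higher in A by a log2 of 0.477 ± 0.0978 SE. A shift of all batch A libraries cannot be told apart from a difference between the pools of lines, because 1 group is in both batches. The lines pooled in each batch are a biological difference that was not tested.

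The change from Wt to sMf flowers was larger in suvh1-2 than in hdp1-1 by a log2 of 0.856 for AGe sense reads and 1.59 for AGe antisense reads, and larger than in hdp2-1 by 1.41 for AGe antisense reads. As given above, each of these calls was lost without certain single libraries and in some alternative settings, and suvh1-2 with Wt flowers had n = 2. The multiply mapped share, which no test used as an outcome, averaged 31.1% in the hdp1-1 ARE//AGe sMf libraries against at most 10.9% in any Col library without a cassette and at most 16.3% in any Col ARE//AGe library. It was not particular to sMf flowers: the share was 24.3% and 30.9% in hdp1-1 ARE//AGe Wt replicates 2 and 3, 33.1% in rMf replicate 2, and 21.5% in suvh1-2 ARE//AGe sMf replicate 3.

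No group had 4 or more libraries, so single libraries were not tested for standing apart from their group.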

How the results depend on the processing

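The alternatives with all mapped reads as library size, exchanged depths, limma, libraries over 20% multiply mapped left out and each library left out alone were added after seeing the data. Of the 144 feature tests, 69 were called. All 69 kept direction and call with both other prior counts, robust moderation, DESeq2 and exchanged depths. Prior counts move fold changes and not p-values by construction, and robust moderation had no more than 4 features to work on, which shows no stability. The replicate block kept all 69. The deviations of same-numbered libraries correlated above 0.1 in 36 of 70 pairs of groups (median 0.105). Each correlation rests on few values and no null distribution was computed, so this cannot tell whether the replicate numbers pair the libraries. Adjustment over all comparisons kept 67, all mapped reads 65 and limma 67. With 1 batch in the fit 62 of 68 were kept, and without libraries over 20% multiply mapped 62 of 63. With only the compared groups in the fit 59 were kept and 6 were new. Without replicates 1, 2 and 3 of all compared groups, 59, 57 and 57 were kept.

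Counts of calls that moved by over 1.5 times follow, and the cause was not tested unless stated. With 1 batch in the fit, AGP//AGe rMf against Ctr//AGe had 2, AGP//AGe Wt against Ctr//AGe 0, and suvh1-2 ARE//AGe sMf against Wt 1. With only the compared groups in the fit, fewer libraries estimate the spread. AGP//AGe rMf against Wt, sMf against rMf, and Wt against Ctr//AGe then had 0, sMf against Ctr//AGe 1, and rMf against Ctr//AGe, ARE//AGe against Ctr//AGe, hdp1-1 against Col and hdp2-1 against Col 2 each. The difference in the sMf change had 0 for suvh1-2 and hdp1-1 and 2 for suvh1-2 and hdp2-1. With all mapped reads, suvh1-2 sMf against Wt had 1, and the difference between suvh1-2 and hdp2-1 had 0. It also had 0 without the libraries over 20% multiply mapped. With limma, AGP//AGe sMf against rMf, hdp1-1 against Col and Col ARE//AGe between batches had 2 each. The sMf difference of suvh1-2 had 1 against hdp1-1 and 0 against hdp2-1, and the cassette differences of hdp1-1 and of hdp2-1 from Col had 4 each. In the first of these, AGp antisense reads reversed to a log2 of 1.33 (limma adjusted p = 0.0488, not called in edgeR), and depends on the pseudocount because Col without a cassette had none. Smaller changes gave 3 for AGP//AGe rMf against Ctr//AGe (all mapped reads, adjustment over all comparisons), hdp1-1 sMf against Col ARE//AGe (all mapped reads), suvh1-2 against Col (1 batch, compared groups, adjustment over all comparisons), Col ARE//AGe against Col (1 batch, compared groups, limma) and the cassette difference of suvh1-2 (1 batch), and of 4 for suvh1-2 ARE//AGe Wt against Col ARE//AGe (compared groups).

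With single replicates or libraries left out, the counts ranged from 0 to 1 for AGP//AGe rMf against Wt and for hdp1-1 rMf against Wt. They ranged from 0 to 2 for AGP//AGe Wt against Ctr//AGe, M318 against Ctr//AGe, suvh1-2 ARE//AGe sMf against Wt, and the sMf differences of suvh1-2 from hdp1-1 and from hdp2-1. They were 1 to 2 for AGP//AGe sMf against rMf, M317 against Ctr//AGe, Col ARE//AGe against Col and the cassette difference of hdp1-1 from Col. They were 2 to 4 for AGP//AGe rMf against Ctr//AGe, 1 to 3 for the cassette difference of suvh1-2, and 2 to 3 for suvh1-2 ARE//AGe Wt against Col ARE//AGe. They were 3 to 4 for suvh1-2 against Col and for hdp1-1 ARE//AGe with sMf and with Wt flowers against Col ARE//AGe. A lone library of a group was assumed to vary like the other groups. Batches could not be compared with 1 batch in the fit, and comparisons with hdp1-1 sMf have no value without the libraries over 20% multiply mapped, since all 3 are among the 7 removed. A test without the filter was void because all 4 features pass it, scaling to the sum of the features was not run with 4 features, and size factors in place of TMM did not apply because library totals were used. Depth limits the promoter region most: a 2-fold change in AGp antisense reads was called in 48% of simulated tables for AGP//AGe sMf against Wt.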

Other observations

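The tests within backgrounds in this part were chosen after the values were seen.

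The share of antisense reads over the enhancer was higher in the 6 Col ARE//AGe libraries, at 45.9% to 73.6%, than in any other library, and the ranges of the other sets overlapped in part. It was 4.50% to 16.2% in the 22 mutant libraries with ARE//AGe, 4.08% to 11.4% in the 9 AGP//AGe libraries, 7.52% to 12.2% in the 3 Ctr//AGe libraries, 5.24% to 8.39% in the 5 M317 and M318 libraries, and 1.08% to 5.41% in the 9 libraries of Col, hdp1-1 and hdp2-1 without a cassette. In suvh1-2 without a cassette it spread from 6.37% to 20.1% over 3 libraries.

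Phenotypes were also compared over all cassette-bearing backgrounds at once, with an exact two-sided permutation of libraries within each background and Benjamini-Hochberg adjustment over 8 tests. For sMf against Wt, promoter reads of both strands were higher in 4 of 4 backgrounds, with a mean log2 difference of 0.46, a permutation p of 0.123 and an adjusted p of 0.329. For rMf against Wt, the antisense share of enhancer reads was higher in 3 of 3 backgrounds by a mean of 2.44 percentage points (permutation p = 0.0908, adjusted p = 0.329). AGe sense reads with rMf flowers differed from Wt by a mean log2 of -0.32, higher in 1 of 3 backgrounds (permutation p = 0.0553, adjusted p = 0.329). None of the 8 tests passed the adjusted threshold.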
